A study of Oryza sativa Japonica Group with 36 samples.

How the data were processed

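RNA of rice leaf blades was measured on one-colour oligonucleotide arrays, with 36 arrays from 4 field conditions on 9 days. The deposited array files hold, per the file headers, spot intensity made by the authors with Agilent Feature Extraction 10.5.1.1, background-subtracted and detrended within the array and not normalized between arrays. The same files hold mean and local background intensity as scanned, and other columns that mark, per the file headers, spots well above background, saturated, uneven or apart from their replicates. The authors also deposited a table of log2 values, which equalled the log2 of the processed intensity less a constant of each array (between -11.2 and -9.78, with an SD within an array of at most 4.45e-10). Each array had 45151 spots, of which 43734 were not controls, and no spot was saturated. Spots marked as uneven or as outliers numbered 24 to 88 per array and were left out, which left 293 probe and array values missing in 211 probes. The 75th percentile of the processed intensity ranged from 904 to 2374, and the fit of the spiked-in transcripts had a squared correlation between 0.997 and 1.00.

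The 42477 probes were joined to rice loci by the array annotation, which gave 41908 probes with a locus and 569 without, and 29690 loci, 7801 of them with 2 or more probes. Values were the log2 processed intensity less the array's 75th percentile. Probes well above background on at least 9 of 36 arrays were kept, and each locus was represented by its brightest probe, which left 22220 loci. Where a called locus had other measured probes, 4 of 157 loci had a probe of the opposite sign between nitrogen-deficient and control leaves, 4 of 141 between nitrogen-deficient and phosphorus-deficient leaves, 2 of 57 for the nitrogen slope and 3 of 110 for the trend. Genes are named by their locus and the description in the array annotation, or by the symbol of their entry in a gene list. Positions are not given.

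The design has 10 comparisons: 6 between pairs of conditions, 3 differences in slope per week between a deficient condition and the control, and the trend with day. Conditions were compared in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with condition and day as factors, fitted to all 36 arrays with 24 residual degrees of freedom and empirical Bayes variances. The days act as the replicates, so that differences are means over 9 days, with 1 array per condition and day. Slopes were fitted as condition by day per week, centred on day 41, and the trend was fitted to the 9 day means of the 4 conditions. A locus was called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Figures were drawn with matplotlib 3.10.9, and files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

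The 31 gene lists comprised 9 lists of loci with 119 entries and 22 lists built from keywords in the array descriptions. The locus lists were phosphate starvation response, nitrogen uptake and assimilation, potassium transport, iron homeostasis, floral transition, circadian clock, chlorophyll breakdown and senescence, pathogenesis-related and phytoalexin, and secondary wall. The keyword for peptide transporters also matches oligopeptide transporters, and the heat shock list includes DnaJ proteins. The entries NRT2.4, HAK21 and Ghd7 had no probe. Lists were tested against the other loci with camera at a preset correlation of 0.01, with p adjusted over the 31 lists of a comparison. An estimated correlation, the self-contained test fry and an exact 2-sided sign-flip test over days, with 512 sign patterns, were alternatives.

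The named loci followed a rule. For each deficiency against the control it took the 8 most positive and 8 most negative loci among those called, with the same sign on at least 8 of 9 days and a functional description. It added up to 10 members of the nutrient's own list by lowest p and up to 4 members of any other list. Slopes took 4 loci in each direction, and the trend took 6 in each direction and the floral transition list. The comparisons, lists, naming rule and first set of alternatives were chosen before the data were examined. Loci named outside the rule are marked as chosen after their values were seen.

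The fit was tested on simulated data with 200 changed loci. The noise was drawn independently for each array, or each day mean for the trend, without slide or scan day effects. It recovered 55.2% of 1.5-fold, 88.1% of 2-fold and 100% of 4-fold changes between nitrogen-deficient and control leaves, and no call had the wrong sign. Recovery was lower for slopes, at 45.5% of 4-fold changes over 8 weeks for the nitrogen slope, and at 31.8% for the trend.

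Alternatives were quantile normalization, scaling to the array median, normexp background correction (offset 50) with quantile normalization, and the deposited log2 values. Further ones were no filter, a filter on all 36 arrays, the mean of a locus's probes, no day term and a linear day term. Others were day as a random block, only the 2 conditions compared (18 arrays), the control alone and early against late days. The last were slide as a random or fixed block and each day left out in turn. Scan day as a block, scan day 1 alone, the fit without the nitrogen-deficient array of day 13, that without day 13 and with the slide as a random block, and the sign-flip test were added after the data were seen. The overlap of responses was compared with 100 simulations of a shared control. For the 10 comparisons, 100 exchanges of conditions within days, or of the order of days for the trend, were drawn. Control spots were left out, and probes without a locus were tested apart.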

Results

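Leaf blades of paddy rice (Oryza sativa, cultivar Nipponbare) were profiled in 4 fields that differed in their basal fertiliser. The control field received nitrogen, phosphate and potash at 55 kg per hectare each, and in each of the 3 deficient fields 1 of these nutrients was omitted. Seedlings about 30 days old were transplanted, and the uppermost fully expanded leaf of the main stem was taken at 12 o'clock on days 13, 20, 27, 34, 41, 48, 55, 62 and 69 after transplanting. Each of the 4 conditions was measured with 1 one-colour oligonucleotide array per day, which gave 9 arrays per condition and 36 in all. Between 67.0% and 76.7% of the spots of an array were well above background, and the number of arrays limits the precision of every value. Nothing in the labels says that the arrays of a condition came from separate plots, so the p-values measure the spread between these leaves and days.

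The arrays were hybridised on 9 slides and read on 4 scan days, which partly follow the conditions. All slides but that of day 20 held a single condition, and within scan day 1 each condition was on 1 slide. Comparisons within scan day 1 thus cannot tell slide and condition apart. Days 13, 27, 41 and 55 of all conditions were read on scan day 1 (16 arrays). Day 20 of all conditions shared 1 slide and was read on scan day 3, together with the later nitrogen-deficient arrays. The later control and phosphorus-deficient arrays were read on scan day 2 (8 arrays), and the later potassium-deficient arrays on scan day 4 (4 arrays). With scan day as a block, differences between conditions therefore rest on days 13, 20, 27, 41 and 55. The exception is phosphorus deficiency against the control, where both conditions of each day shared a scan day. The mean share of spots well above background was 74.1%, 71.2%, 68.7% and 70.0% on scan days 1 to 4.

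The largest component of variation between the arrays followed the day of sampling. The first principal component held 33.7% of the variance across 22220 loci, and its score on day 69 lay between 86.4 and 99.4 in all 4 conditions. On day 20 the same score lay between -91.6 and -48.6. The nitrogen-deficient leaf of day 13 stood apart, with a score of 85.8 against -37.6 in the control leaf of that day, and 27.6% of its loci differed from that leaf by 2-fold or more.

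**Figure D1:**
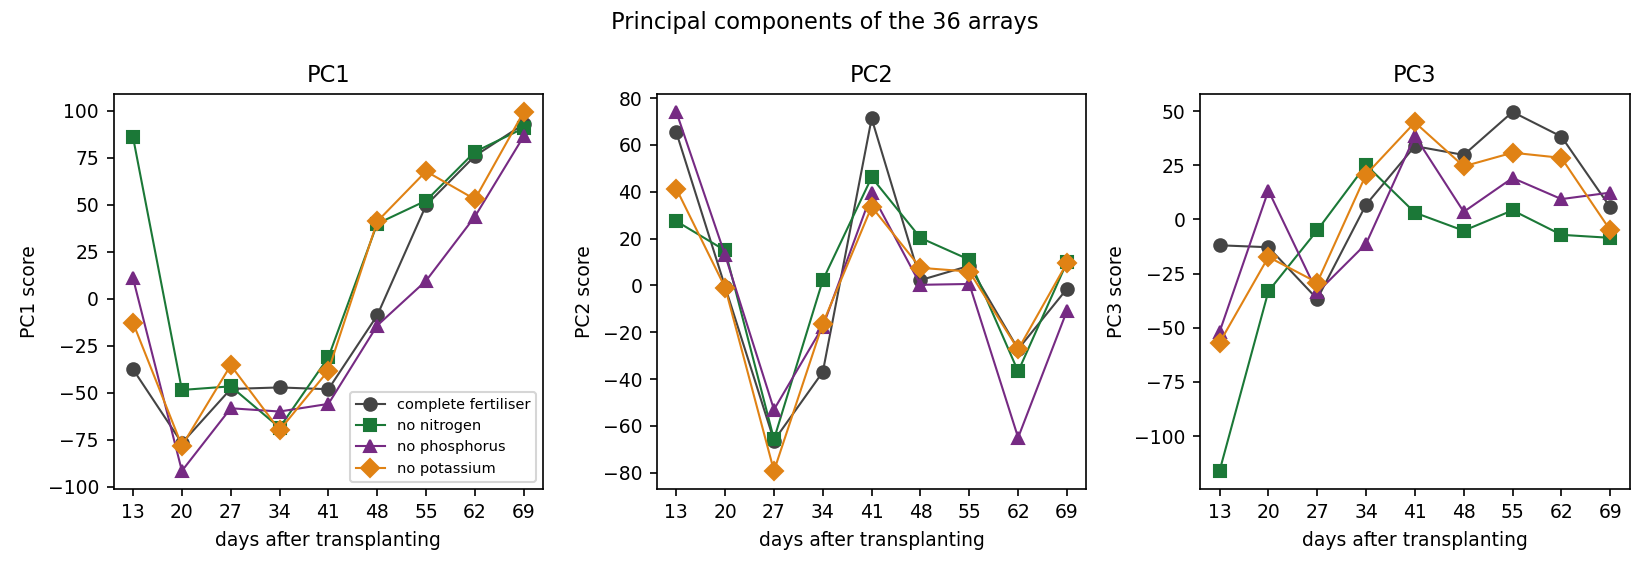
Scores of the 36 arrays on the first 3 principal components (vertical axes, no unit) against days after transplanting (horizontal axes), with 1 symbol per array and 1 line per condition. Scores on the first component rise to between 86.4 and 99.4 on day 69, and the nitrogen-deficient leaf of day 13 lies at 85.8 on the first and -116 on the third component.

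Nitrogen-deficient leaves were compared with control leaves of the same days, a comparison that addresses the transcript response to nitrogen left out of the fertiliser. Genes that handle nitrogen were among those that rose. L-asparaginase (Os03g0597600), which releases ammonium from asparagine, was higher by 1.2 ± 0.29 on the log2 scale (higher on 9 of 9 days). Here and below, ± gives the limma SE, whose residual spread is taken over all conditions. Ferredoxin-nitrite reductase (Os01g0357100, the NiR1 entry of the nitrogen list) rose by 0.65 ± 0.17 on the log2 scale and nitrate reductase (Os08g0468700, the NIA2 entry) by 0.61 ± 0.16. Expansins, which loosen cell walls, were among the loci that fell: expansin S2 (Os04g0228400) by -1.88 ± 0.39 and a beta-expansin (Os03g0102700) by -1.94 ± 0.45. Endochitinase A (Os04g0494100) fell by -2.18 ± 0.42.

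Across the 22220 loci, 446 passed an adjusted p of 0.05 in limma with day as a factor, 165 higher and 281 lower in nitrogen-deficient leaves. Of these, 108 differed by 2-fold or more, 10 higher and 98 lower. At an unadjusted p under 0.05 there were 4196 loci, where 1111 are awaited by chance. The highest named locus was a flavin monooxygenase-like gene (Os12g0512000), 3.17-fold higher (log2 1.67 ± 0.37, adjusted p = 0.0222, 8 of 9 days). A cytochrome P450 (Os04g0339000, log2 1.63), a receptor-like kinase (Os04g0633800, 1.39), a dimethyladenosine transferase-like gene (Os07g0509600, 1.12), a protein kinase (Os12g0603700, 1.07), glutathione-S-transferase 2 (Os10g0529700, 1.03) and a Myb factor (Os05g0579600, 0.98) were also higher. The lowest was a glycoside hydrolase of family 18 (Os05g0247100), with a log2 difference of -2.35 ± 0.56 (adjusted p = 0.0307, lower on every day). Protochlorophyllide reductase A (Os04g0678700), which makes a chlorophyll precursor in light, was at -2.07 ± 0.51. A class B acid phosphatase (Os05g0191500, -2.04), a jacalin-related lectin (Os01g0348900, -1.88) and a protein of the pollen allergen Lol pI family (Os10g0555700, -1.84) were lower as well.

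The count moved with the days and blocks in the fit. Without day 13 the count was 244, without day 20 it was 729, without day 27 it was 1056, without day 41 it was 186, without day 48 it was 13, without day 55 it was 183, without day 62 it was 42 and without day 69 it was 78. None of the 16 named loci passed when day 48 was left out, although all 16 had the same sign. With scan day as a block 7 loci passed, within scan day 1 alone 3 loci passed, none of them among the 446, and with the slide as a random block 6 loci passed. The later nitrogen-deficient arrays have no control array of the same day on their scan day. The scan day block thus rests on days 13, 20, 27, 41 and 55, and is not a separate check from scan day 1 alone. With only the 2 conditions compared 0 loci passed. That fit left 8 residual degrees of freedom, with a median absolute difference of 0.63 and a median SE of 0.16 over the 446. Under the scan day block all 446 loci, which were chosen on the same arrays, had the same sign and 403 an unadjusted p under 0.05. Their median absolute difference was 0.57 against 0.63 and their median SE 0.18 against 0.15. Under that block the 16 named loci kept their sign with adjusted p between 0.0953 and 0.264, and 6 of the 16 passed without the nitrogen-deficient array of day 13. With the slide as a fixed block, which rests on the day-20 slide with 1 array per condition, several of the 16 turned sign.

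**Figure D2:**
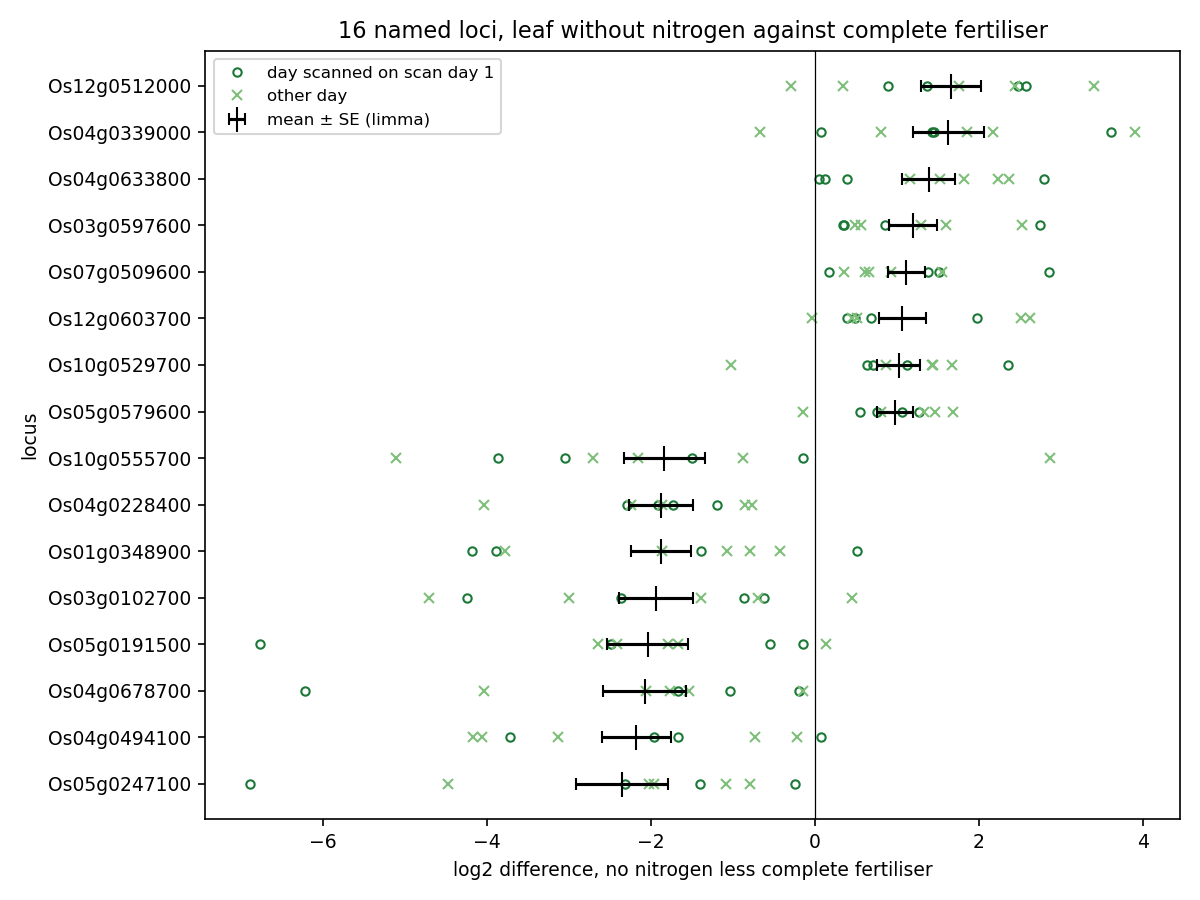
Log2 difference of nitrogen-deficient less control leaves (horizontal axis) for the 16 named loci (vertical axis). Circles are the 4 days read on scan day 1, crosses the other 5 days, and the black marks with bars the limma mean and its SE; Os05g0247100 lies lowest at -2.35 and Os12g0512000 highest at 1.67.

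The nitrogen uptake and assimilation list had 25 measured loci, of which 2 rose, NiR1 and NIA2, and 6 rose and 2 fell when adjusted over the list alone. The lower loci were AS1 (asparagine synthetase, Os03g0291500, log2 -1.34 ± 0.49) and AMT2.1 (ammonium transporter, Os05g0468700, -0.30 ± 0.11), neither of which passed over all loci. NIA1 (Os08g0468100) had a difference of 0.50 ± 0.16, AMT1.1 (Os04g0509600) 0.59 ± 0.21 and AS2 (Os06g0265000) 0.33 ± 0.12. The list as a whole had a median of 0.15 and did not pass camera (adjusted p = 0.0971). It stood at 0.21 with scan day as a block (adjusted p = 0.0678) and at 0.29 within scan day 1, where it passed (adjusted p = 0.0373). NiR1 and NIA2 had adjusted p of 0.18 and 0.154 with the block, and 0.0885 and 0.0548 without the nitrogen-deficient array of day 13.

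Of the 31 lists, 10 passed camera with its preset correlation in this comparison, and none of them with an estimated correlation. Chlorophyll breakdown and senescence genes were higher, with a median of 0.61 over 5 loci (adjusted p = 0.0143; adjusted p = 0.365 with an estimated correlation). None of the 5 passed over all loci and 3 did adjusted over the list alone: NAP (Os03g0327800, a senescence-linked NAC factor, 1.05 ± 0.32), RCCR1 (Os10g0389200, red chlorophyll catabolite reductase, 0.90 ± 0.29) and SGR (Os09g0532000, 0.61 ± 0.19). Expansins were lower, with a median of -0.57 over 22 loci (adjusted p = 1.56e-07; adjusted p = 0.365 with an estimated correlation), of which 3 fell over all loci and 9 adjusted over the list alone. Class III peroxidases had a median of -0.38 over 41 loci (adjusted p = 1.79e-06; adjusted p = 0.365 with an estimated correlation), and 3 fell, among them peroxidase 1 (Os01g0327400, -0.60 ± 0.13) and peroxidase 72 (Os01g0543100, -1.14 ± 0.25), against 9 adjusted over the list alone. The 17 lipid transfer proteins had a median of -0.39 (adjusted p = 3.81e-05; adjusted p = 0.365 with an estimated correlation); LPT II (Os12g0115000) fell by -1.25 ± 0.33, and 7 fell and 1 rose adjusted over the list alone. The 2 cellulose synthases of the secondary wall list, which marks vascular tissue, had differences of -2.67 ± 0.80 (CESA7, Os10g0467800) and -1.73 ± 0.58 (CESA4, Os01g0750300). Their list had adjusted p = 0.0143, or adjusted p = 0.365 with an estimated correlation, and both passed adjusted over the list alone. Within scan day 1 the list had adjusted p = 0.0809 (median -2.70).

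The purple acid phosphatase and phosphodiesterase lists were also lower in nitrogen-deficient leaves, while the phosphate starvation response (median -0.09, adjusted p = 0.0876) and SPX domain proteins (0.04, 0.977) did not pass. The phosphate list was lower and passed with scan day as a block (-0.34, adjusted p = 0.0167), and had adjusted p = 0.0646 within scan day 1 (-0.39) and 0.773 without the nitrogen-deficient array of day 13 (-0.05). The 9 glycerophosphodiester phosphodiesterases, which release glycerol phosphate from membrane lipids, had a median of -0.52 (adjusted p = 0.000745; adjusted p = 0.365 with an estimated correlation). Os02g0588500 of that list fell by -1.88 ± 0.46, and 2 fell adjusted over the list alone. The 11 purple acid phosphatases had a median of -0.44 (adjusted p = 0.00985; adjusted p = 0.473 with an estimated correlation); Os07g0111600 fell by -0.49 ± 0.13 and was also the 1 call adjusted over the list alone. The 30 jasmonate genes had a median of -0.15 with no call over all loci or adjusted over the list alone (adjusted p = 0.0256; adjusted p = 0.599 with an estimated correlation). Without the nitrogen-deficient array of day 13, the purple acid phosphatases had adjusted p = 0.138 (median -0.31), the jasmonate list 0.101 (-0.09) and the chlorophyll breakdown list 0.0503 (0.46). The phosphodiesterases then stood at -0.24 and the peroxidases at -0.25. A scan day block put the lipid transfer proteins at -0.71 and the jasmonate genes at -0.09. Within scan day 1 the purple acid phosphatases had adjusted p = 0.0809 (median -0.45) and the jasmonate genes 0.246 (-0.06), and the lipid transfer proteins stood at -0.87.

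Ribosomal proteins and the histone and cyclin list, which marks dividing cells, were higher. The 297 ribosomal proteins had a median of 0.20 with no call over all loci or adjusted over the list alone (adjusted p = 1.56e-07; adjusted p = 0.599 with an estimated correlation), and 0.12 without the nitrogen-deficient array of day 13. The 45 histones and cyclins had a median of 0.24 (adjusted p = 6.22e-06; adjusted p = 0.473 with an estimated correlation). A histone H2B (Os01g0152900) rose by 0.36 ± 0.09, and 8 rose adjusted over the list alone. The histone median with a scan day block was 0.06 (adjusted p = 0.672) and within scan day 1 it was 0.06 (adjusted p = 0.466). In exact 2-sided sign-flip tests over the 9 days, adjusted over the 31 lists, none of the 10 passed. The smallest p that 9 days allow is 0.00391 unadjusted, so that a single list cannot pass after adjustment and this test decides little.

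The other 21 lists did not pass in this fit, with adjusted p from 0.0876 to 0.977. They were phosphate starvation response, nitrogen uptake and assimilation, potassium transport, iron homeostasis, floral transition, circadian clock, pathogenesis-related and phytoalexin, SPX domain proteins, nitrate and peptide transporters, potassium transporters and channels, chlorophyll a/b-binding proteins, photosystem subunits, Rubisco and Calvin cycle, heat shock proteins, WRKY factors, glutathione S-transferases, terpene synthases, flavonoid synthesis, aquaporins, starch synthesis and autophagy. Their medians lay between -0.25 (starch synthesis) and 0.21 (chlorophyll a/b-binding proteins). A scan day block gave 5 calls among the 21, all lower: the phosphate list, chlorophyll a/b-binding proteins (-0.21, adjusted p = 0.00198), photosystem subunits (-0.21, 0.000112), terpene synthases (-0.13, 0.0467) and flavonoid synthesis (-0.27, 0.00662). The last 4 and the nitrogen list also passed within scan day 1. With the nitrogen-deficient array of day 13 left out, the chlorophyll a/b-binding proteins (0.36, adjusted p = 0.00336), photosystem subunits (0.23, 0.00202), Calvin cycle genes (0.19, 0.0242) and circadian clock (0.11, 0.0239) passed as higher, so the sign of the first 2 depends on the fit.

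Phosphorus-deficient leaves were compared with control leaves to measure the response to phosphate left out. The phosphate starvation response list, which holds genes linked to phosphate shortage and not only induced ones, was higher, with a median log2 difference of 0.36 over 19 loci. It passed camera with adjusted p = 0.00383, and had adjusted p = 0.983 with an estimated correlation. Its members with the largest values were IPS1 (Os03g0146800, a non-coding RNA of phosphate signalling) at 1.71 ± 0.78 and MGD2 (Os08g0299400, a galactolipid synthase) at 1.48 ± 0.90. SPX3 (Os10g0392600) at 1.08 ± 0.83 and GDPD2 (Os02g0514500) at 1.05 ± 0.55 followed (limma SE). None of the 19 loci passed by itself, over all loci or adjusted over the list alone.

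The mean over members of this list was positive on 7 of 9 days and ranged from -0.29 on day 13 to 1.92 on day 55, without which the mean of 0.45 was 0.26. An exact 2-sided sign-flip test over the 9 days gave p = 0.0391, and 0.606 adjusted over the 31 lists. Both conditions of each day shared a scan day, so a scan day block left the medians as they were, with adjusted p = 0.0107 for this list and 0.024 for the histones. The phosphate list had a median of 0.35 within scan day 1 (adjusted p = 0.0131). The histone and cyclin list was lower, with a median of -0.10 over 45 loci (adjusted p = 0.0411; adjusted p = 0.983 with an estimated correlation), and within scan day 1 it stood at -0.06 (adjusted p = 0.565). The other lists did not pass in this fit, but the ribosomal proteins were higher within scan day 1 (0.17, adjusted p = 7.2e-07), and the expansins (-0.24, adjusted p = 0.056) passed under array median scaling (0.0264) and without the nitrogen-deficient array of day 13 (0.038). No locus of the 22220 passed in limma, and 1109 had an unadjusted p under 0.05, where 1111 are awaited by chance. In simulated data with independent noise and no slide or scan day effects, the same fit recovered 86.6% of 2-fold changes. IPS1, MGD2 and SPX3 differed by more than 2-fold and were not called, so that share is no guide for loci with so large an SE.

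**Figure D3:**
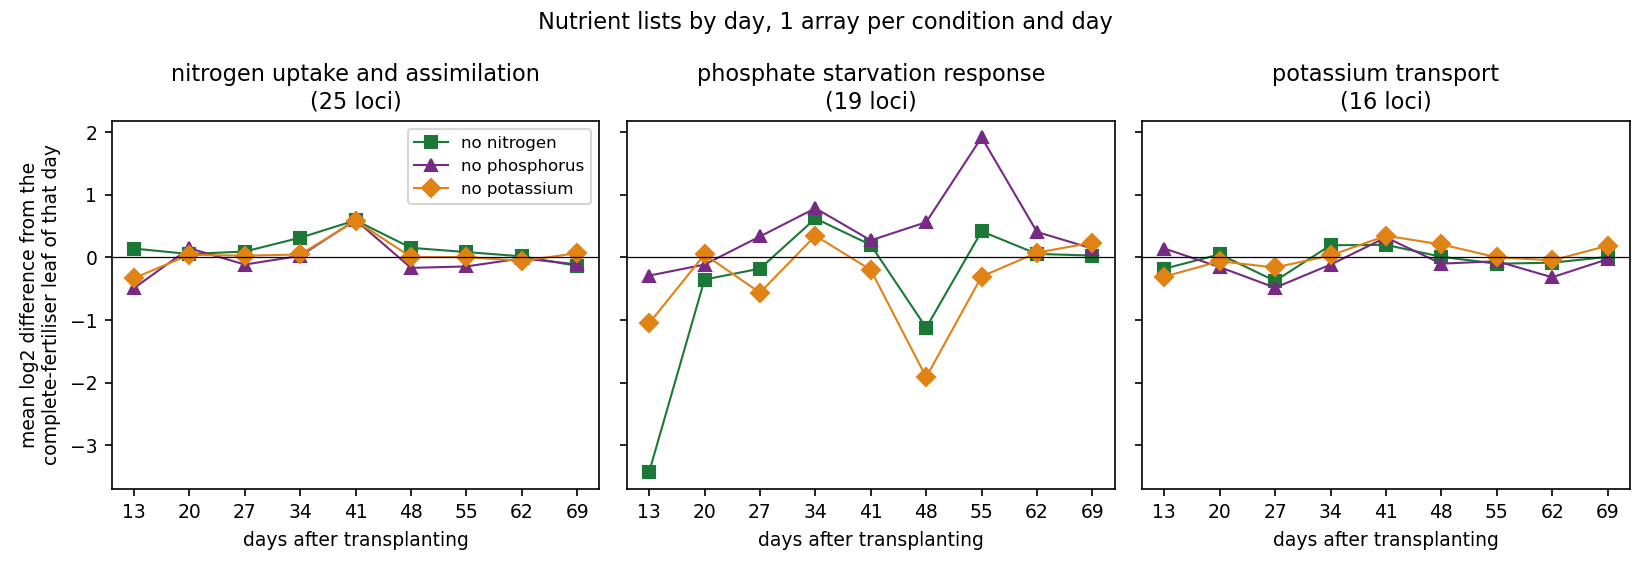
Mean log2 difference from the control leaf of the same day (vertical axis) over the 25 nitrogen, 19 phosphate and 16 potassium list loci, against days after transplanting, with 1 array per condition and day. The phosphate list of phosphorus-deficient leaves reaches 1.92 on day 55, while that of nitrogen-deficient leaves lies at -3.43 on day 13 and that of potassium-deficient leaves at -1.91 on day 48.

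Potassium-deficient leaves were compared with control leaves in the same way. The potassium transport list did not pass, with a median of -0.02 over 16 loci (camera, adjusted p = 0.796), and none of its members was called over all loci or adjusted over the list alone. A K+ transporter of the HAK family (Os01g0930400, the HAK5 entry) had a difference of 0.50 ± 0.20, higher on 7 of 9 days, with adjusted p = 0.702. Another HAK-type transporter (Os06g0625900) stood at 0.29 ± 0.19. The 9 glycerophosphodiester phosphodiesterases were lower in camera, with a median of -0.49 (adjusted p = 0.0114; adjusted p = 0.795 with an estimated correlation, and 0.274 with scan day as a block at a median of -0.30). The 22 expansins were lower too, with a median of -0.15 (adjusted p = 0.0303; adjusted p = 0.795 with an estimated correlation).

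In camera the purple acid phosphatases (median -0.23, adjusted p = 0.0169) and the lipid transfer proteins (-0.19, 0.0169) were lower, and the histone and cyclin list (0.11, 0.0114) higher, each at adjusted p = 0.795 with an estimated correlation. The ribosomal proteins (0.07, adjusted p = 0.0194) had adjusted p = 0.854 with an estimated correlation. With scan day as a block the expansins stood at -0.41 (adjusted p = 0.000392) and the lipid transfer proteins at -0.32 (0.00015). The same block gave adjusted p of 0.0933 for the purple acid phosphatases, 0.058 for the ribosomal proteins and 0.506 for the histones, whose median turned to -0.02. Within scan day 1 adjusted p was 0.433 for the phosphodiesterases, 0.263 for the purple acid phosphatases and 0.486 for the histones, while the ribosomal proteins (0.14, adjusted p = 0.00429), expansins (-0.48, 0.00639) and lipid transfer proteins (-0.42, 0.00429) passed. Of the lists not called in the reported fit, the chlorophyll a/b-binding proteins (-0.20, adjusted p = 0.00723), photosystem subunits (-0.18, 0.00149), peroxidases (-0.31, 0.000881) and flavonoid synthesis (-0.22, 0.0103) passed as lower with the block, and within scan day 1 as well. The phosphate list (-0.23, adjusted p = 0.0694) passed without the nitrogen-deficient array of day 13 (0.0134). Adjusted over the list alone, 1 expansin fell and no member of the other 5 lists was called.

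No single locus passed in limma between potassium-deficient and control leaves, and 1446 had an unadjusted p under 0.05. With scan day as a block 1 locus passed, and within scan day 1 alone 151 passed, 2 higher and 149 lower. Within scan day 1 each of the conditions was on 1 slide, so slide and potassium deficiency cannot be told apart there.

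The overlap of the 3 responses was 0 loci, since only nitrogen deficiency gave calls against the control. Across loci, which are not independent replicates, the differences of nitrogen-deficient and potassium-deficient leaves from the control correlated at 0.626. Those of nitrogen and phosphorus deficiency correlated at 0.297, and those of phosphorus and potassium deficiency at 0.407. The shared control alone gave a median of 0.602 in 100 simulations (0.119 to 0.854, 95% range), so none of the 3 lay outside it. With the days split between the 2 responses, so that each had control and deficient leaves of different days, the correlations lay between -0.183 and 0.070. All days of scan day 1 fell in the same part, so the split changed the scan day along with the control and cannot separate the 2. No locus was then called in both responses with the same sign. Phosphorus and potassium deficiency gave no calls even over all days, so this count decides little.

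Nitrogen-deficient leaves were next compared directly with phosphorus-deficient leaves, which tests the difference between these responses. IPS1 (Os03g0146800) was lower by -3.27 ± 0.78 and SPX3 (Os10g0392600) by -3.22 ± 0.83 on the log2 scale. Genes of nitrogen assimilation rose: NiR1 (Os01g0357100) by 0.85 ± 0.17, NiR2 (Os02g0765900) by 0.75 ± 0.17, GS1.1 (glutamine synthetase, Os02g0735200) by 0.50 ± 0.12, AS2 (Os06g0265000) by 0.45 ± 0.12 and DUR3 (urea transporter, Os10g0580400) by 1.37 ± 0.37. AS1 (Os03g0291500) fell by -1.92 ± 0.49 and NAP (Os03g0327800) was higher by 1.44 ± 0.32.

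The nitrogen uptake and assimilation list had a median of 0.19 (adjusted p = 0.0216; adjusted p = 0.394 with an estimated correlation), with 5 higher and 1 lower over all loci and 10 and 4 adjusted over the list alone. The phosphate starvation response list had a median of -0.34 (adjusted p = 0.000101; adjusted p = 0.394 with an estimated correlation), with 2 lower over all loci and 7 adjusted over the list alone. It was lower on 9 of 9 days, for which an exact 2-sided sign-flip test gave p = 0.00391, the smallest that 9 days allow, and 0.0605 adjusted over the 31 lists. With scan day as a block its median was -0.70 (adjusted p = 4.31e-05) and within scan day 1 it was -0.71 (adjusted p = 5.95e-06). Without the nitrogen-deficient array of day 13 it was -0.17 (adjusted p = 0.00519). The nitrogen list stood at 0.29 with the block (adjusted p = 0.0177) and at 0.25 within scan day 1 (adjusted p = 0.00629). Under quantile normalization it did not pass (0.19, adjusted p = 0.0777).

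A further 10 lists passed camera. The histones and cyclins (median 0.32, adjusted p = 8.4e-10) and chlorophyll breakdown (0.68, 0.0274) were higher, both at adjusted p = 0.394 with an estimated correlation. The ribosomal proteins were higher too (0.19, adjusted p = 1.08e-05; adjusted p = 0.687 with an estimated correlation). Lower were the phosphodiesterases (-1.14, adjusted p = 0.000104), purple acid phosphatases (-0.58, 0.000423), peroxidases (-0.28, 0.00036), expansins (-0.40, 0.00036) and secondary wall genes (-1.91, 0.0286), all at adjusted p = 0.394 with an estimated correlation. The lipid transfer proteins (-0.20, adjusted p = 0.0112) had adjusted p = 0.475 with an estimated correlation, and the jasmonate genes (-0.11, 0.0381) adjusted p = 0.575 with an estimated correlation. Fitted with a scan day block, the chlorophyll breakdown list had adjusted p = 0.0531, the histones 0.0507 and the secondary wall genes 0.0505. Over all loci 3 histones were higher, among them a histone H2B (Os01g0502900, 0.43 ± 0.10), and 27 of the 45 adjusted over the list alone. Adjusted over the list alone, 4 phosphodiesterases, 4 purple acid phosphatases, 5 expansins, 2 peroxidases, 2 lipid transfer proteins, 2 jasmonate genes and both secondary wall genes were lower, and 3 chlorophyll breakdown genes and 1 ribosomal protein higher. Over all loci these counts were 0, 1, 2, 0, 1, 1, 0, 1 and 2. Without the nitrogen-deficient array of day 13, the lipid transfer proteins had adjusted p = 0.174, the jasmonate genes 0.115, the chlorophyll breakdown list 0.0694 and the secondary wall genes 0.0604. Medians that moved by over 1.5 times without it were -0.63 for the phosphodiesterases, -0.18 for the peroxidases, -0.25 for the expansins, 0.11 for the ribosomal proteins, -0.04 for the jasmonate genes and 0.31 for the nitrogen list. A scan day block put the histones at 0.16 and the lipid transfer proteins at -0.47. Within scan day 1 adjusted p was 0.144 for the histones, 0.0551 for the jasmonate genes and 0.0964 for the secondary wall genes. Gained under the block and within scan day 1, as lower, were chlorophyll a/b-binding proteins (-0.14 and adjusted p = 0.00924 with the block), photosystem subunits (-0.14, 0.00214) and flavonoid synthesis (-0.15, 0.0464). The first 2 passed as higher without the nitrogen-deficient array of day 13 (0.39, adjusted p = 0.00299, and 0.27, 0.00054), and starch synthesis passed as lower under quantile normalization (-0.41, 0.0459).

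In all, 441 loci passed between nitrogen-deficient and phosphorus-deficient leaves in limma, 246 higher and 195 lower, of 4687 at an unadjusted p under 0.05. The count was 1085 without day 27, 209 without day 34, 0 without day 48, 97 without day 55, 67 without day 62 and 101 without day 69. It was 213 without the nitrogen-deficient array of day 13. With scan day as a block, within scan day 1 alone and with the slide as a random block no locus passed.

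Between nitrogen-deficient and potassium-deficient leaves, 2 loci passed in limma, both lower, and both are named after their values were seen. A VQ domain protein (Os05g0491700) had a log2 difference of -1.02 ± 0.17 and a SigA binding protein (Os01g0808900) one of -0.84 ± 0.14, each at adjusted p = 0.0216. Their mean level in nitrogen-deficient leaves was -4.76 and -1.82, against -3.74 and -0.97 in potassium-deficient leaves. Without day 20 the count was 8, without days 34 or 55 it was 1, and without days 13, 41, 48, 62 or 69 it was 0. It was 0 without the nitrogen-deficient array of day 13, with scan day as a block and with the slide as a random block, and 1 within scan day 1, and 2375 loci had an unadjusted p under 0.05.

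Of the lists, 9 passed camera here. Terpene synthases were lower on 9 of 9 days (median -0.25 over 19 loci, adjusted p = 0.0109; adjusted p = 0.2 with an estimated correlation), with no member called over all loci or adjusted over the list alone. An exact 2-sided sign-flip test gave p = 0.00391 for them, and 0.121 adjusted over the 31 lists. Expansins (-0.34, adjusted p = 7.97e-06), peroxidases (-0.31, 7.97e-06) and secondary wall genes (-1.68, 0.0213) were lower and chlorophyll breakdown genes (0.45, 0.0128) higher, all at adjusted p = 0.432 with an estimated correlation. Adjusted over the list alone, 2 peroxidases and both secondary wall genes were lower and 2 chlorophyll breakdown genes higher, and over all loci no member of the 9 lists was called. Jasmonate genes (-0.14, adjusted p = 0.0187) and lipid transfer proteins (-0.22, 0.0128) had adjusted p = 0.79 with an estimated correlation. Histones (0.11, adjusted p = 0.0109) had adjusted p = 0.794 with an estimated correlation, and ribosomal proteins (0.12, 6.93e-05) adjusted p = 0.82 with an estimated correlation. Without the nitrogen-deficient array of day 13, the chlorophyll breakdown list had adjusted p = 0.0816, the ribosomal proteins 0.406, the jasmonate genes 0.206, the lipid transfer proteins 0.349 and the secondary wall genes 0.0794, and the expansin median was -0.22. The block for scan day gave adjusted p = 0.252 for the histones and 0.116 for the secondary wall genes. The same block put the chlorophyll breakdown list at 0.73, the jasmonate genes at -0.37, the lipid transfer proteins at -0.35 and the ribosomal proteins at 0.20. Within scan day 1 adjusted p was 0.994 for the histones and 0.0827 for the secondary wall genes, and quantile normalization gave 0.061 for the histones (0.07). Iron homeostasis (-0.61, adjusted p = 0.0345) and the phosphodiesterases (-0.34, 0.0166) passed as lower only with the block and within scan day 1. SPX domain proteins (0.26, adjusted p = 0.0331), chlorophyll a/b-binding proteins (0.23, 0.034) and photosystem subunits (0.19, 0.0213) passed as higher only without that array.

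Phosphorus-deficient leaves had higher phosphate starvation response values than potassium-deficient leaves. The median over the 19 loci was 0.62, and 8 were higher adjusted over the list alone, among them IPS1 (Os03g0146800, 2.62 ± 0.78), MGD2 (Os08g0299400, 2.64 ± 0.90) and SPX3 (Os10g0392600, 2.61 ± 0.83). Over all 22220 loci none passed in limma, and 2086 had an unadjusted p under 0.05. The list had adjusted p = 1.65e-06 in camera and adjusted p = 0.626 with an estimated correlation. Its median was 0.49 with scan day as a block (adjusted p = 0.000317) and 0.60 within scan day 1 (adjusted p = 2.17e-05). Purple acid phosphatases (0.36, adjusted p = 0.000407) and phosphodiesterases (0.25, 0.000792) were higher and histones lower (-0.19, 2.28e-07), all at adjusted p = 0.626 with an estimated correlation. Adjusted over the list alone, 3 phosphodiesterases were higher and 1 histone lower. Under the scan day block the phosphodiesterases had adjusted p = 0.0643 and the histones 0.486 (median -0.03), and within scan day 1 they had 0.0815 and 0.124. Lists gained with the block, as higher, were chlorophyll a/b-binding proteins (0.14, adjusted p = 0.041), photosystem subunits (0.12, 0.041), peroxidases (0.21, 0.0422) and lipid transfer proteins (0.21, 0.0306). Within scan day 1 SPX domain proteins (0.45), expansins (0.30) and lipid transfer proteins (0.24) passed as higher and the nitrogen list (-0.15) as lower, each at adjusted p = 0.0338. With the nitrogen-deficient array of day 13 left out, SPX domain proteins (adjusted p = 0.0178) and starch synthesis (0.0224) passed as higher and the nitrogen list (0.0281) as lower, and under quantile normalization the ribosomal proteins (-0.08, 0.0278) as lower. The block gave 1 locus over all, scan day 1 alone gave 6, and leaving out day 20 gave 1.

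The change of the nitrogen difference over the season was tested next, as the slope per week of nitrogen-deficient less control leaves. A gene of the FLOWERING LOCUS T family (Os04g0488400) rose by 0.57 ± 0.14 per week relative to the control and a MADS box gene (Os03g0753100) by 0.59 ± 0.12. A protein kinase (Os09g0341100, 1.01 ± 0.24) and a phosphate-induced protein (Os02g0756800, 0.54 ± 0.13) rose as well. An EB1-type gene (Os10g0498900) fell by -0.72 ± 0.14 per week, and a PHD finger gene (Os03g0716200, -0.48), a HAP2 factor (Os12g0618600, -0.45) and a leucine-rich repeat gene (Os01g0132100, -0.41) were lower.

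In limma 231 loci passed for this slope, 161 higher and 70 lower, of 4572 at an unadjusted p under 0.05. The count was 2 without the nitrogen-deficient array of day 13, and 0 with scan day as a block and within scan day 1. It was 7 without day 13, 24 without day 20, 977 without day 34, 589 without day 41, 84 without day 48, 2 without day 62 and 21 without day 69. Photosystem subunits (median slope 0.11, adjusted p = 0.000191), chlorophyll a/b-binding proteins (0.13, 0.00293), Rubisco and Calvin cycle genes (0.10, 0.0115), the phosphate starvation response (0.15, 0.0108) and purple acid phosphatases (0.10, 0.0115) had positive slopes in camera, all at adjusted p = 0.826 with an estimated correlation. The ribosomal proteins had a median of -0.04 (adjusted p = 0.0115; adjusted p = 0.893 with an estimated correlation). Without day 13 the phosphate list stood at -0.01 and the ribosomal proteins at 0.07, and under quantile normalization the 3 photosynthesis lists stood at 0.02, 0.02 and 0.01. No member of these 6 lists was called over all loci. Adjusted over the list alone, 4 chlorophyll a/b-binding proteins, 2 Calvin cycle genes, 2 purple acid phosphatases and 1 phosphate list gene were called, all higher.

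For phosphorus deficiency the slope was called at 3 loci in limma, and 1585 had an unadjusted p under 0.05. A glucosyltransferase (Os02g0578100) rose by 0.39 ± 0.07 per week relative to the control (adjusted p = 0.029), and an NF-YA subunit (Os03g0647600) fell by -0.30 ± 0.05 (adjusted p = 0.0238). The other, named after its values were seen, was a non-coding transcript (Os09g0458500, 0.38 ± 0.06). The count was 0 without day 13, 1 without day 27, 0 without day 62, 21 without day 69, 7 without the nitrogen-deficient array of day 13 and 0 within scan day 1. The histones and cyclins had a median slope of -0.07 (adjusted p = 1.83e-10; adjusted p = 0.961 with an estimated correlation), with no member called over all loci or adjusted over the list alone. For potassium deficiency no locus and no list had a called slope, and 1189 loci had an unadjusted p under 0.05 in limma.

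The trend with day was taken over the 9 day means of the 4 conditions and asks which leaf transcripts change with the season. Of the floral transition list, MADS1 (Os03g0215400) rose by 1.04 ± 0.11 on the log2 scale per week and MADS18 (Os07g0605200) by 0.32 ± 0.06. A MOTHER of FT gene (Os06g0498800) rose by 1.17 ± 0.20, and a gene of the phosphatidylethanolamine-binding family (Os01g0748800) by 0.91 ± 0.14. Phenylalanine ammonia-lyases, which open phenylpropanoid synthesis, fell at Os12g0520200 by -0.90 ± 0.13 and at Os11g0708900 by -0.88 ± 0.13, and GDPD2 (Os02g0514500) by -0.88 ± 0.17.

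In this fit 434 loci passed in limma, 284 higher and 150 lower, of 5015 at an unadjusted p under 0.05. A beta-1,3-glucanase (Os01g0946600, 0.90 per week) and an O-methyltransferase (Os09g0344500, 0.89) were also higher, and a protein kinase (Os11g0113700, -1.27), a carboxypeptidase (Os03g0386800, -0.87) and a Bowman-Birk inhibitor (Os03g0823400, -0.86) lower. MADS1 was well above background on 23 of 36 arrays, the MOTHER of FT gene on 22, the O-methyltransferase on 26, the glucanase on 24 and Os01g0748800 on 14. The early levels of these rising loci lay near background, as did the late levels of the kinase Os11g0113700 (27 of 36 arrays above it) and the carboxypeptidase Os03g0386800 (32 of 36), so that the slopes of all 7 are approximate. Loci of the floral transition list that were not called were Hd1 (Os06g0275000, 0.07), MADS14 (Os03g0752800, 0.08), MADS15 (Os07g0108900, -0.09), MADS50 (Os03g0122600, -0.06) and GI (Os01g0182600, -0.05). The list as a whole did not pass camera (adjusted p = 0.0792). The ammonium transporter AMT1.3 (Os02g0620600) rose by 0.29 ± 0.04 per week.

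**Figure D4:**
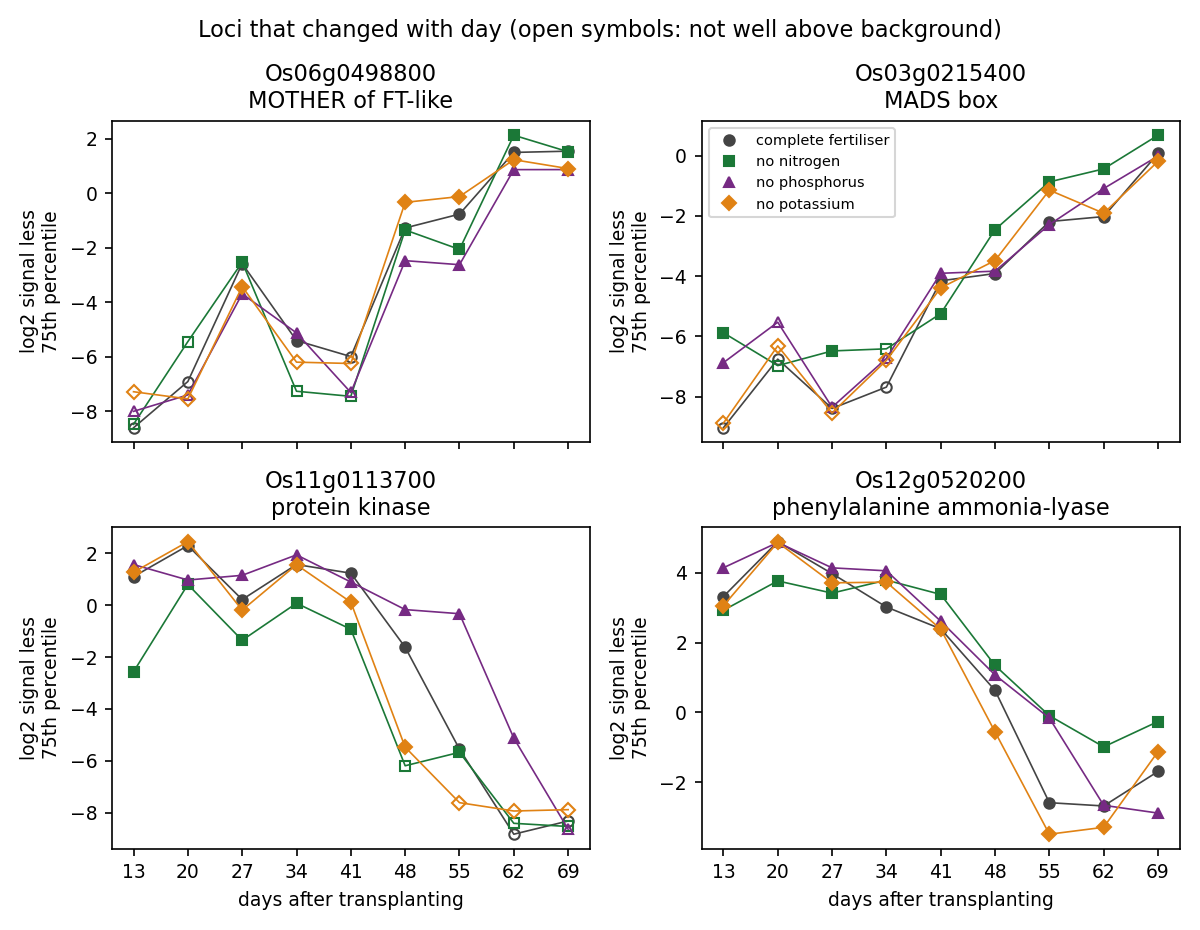
Log2 signal less the array's 75th percentile (vertical axes) against days after transplanting for 4 loci, with 1 symbol per array and 1 line per condition; open symbols are not well above background. In the upper panels levels rise by 1.17 and 1.04 per week, and in the lower panels they fall, with slopes of -1.27 and -0.90.

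Photosystem subunits declined with day, with a median of -0.12 per week over 34 loci (camera, adjusted p = 8.03e-09; adjusted p = 0.629 with an estimated correlation). Over all loci 4 fell, among them genes of the photosystem II CP47 protein (Os06g0598100, -0.28 ± 0.04, and Os08g0252100, -0.29 ± 0.04), against 12 lower and 1 higher adjusted over the list alone. Chlorophyll a/b-binding proteins (-0.11, adjusted p = 0.000111), Rubisco and Calvin cycle genes (-0.07, 0.00228), the phosphate starvation response (-0.30, 4.37e-06), SPX domain proteins (-0.28, 0.0434), purple acid phosphatases (-0.18, 0.00432) and phosphodiesterases (-0.13, 0.0215) were lower and the histones and cyclins higher (0.11, 2.39e-05), all at adjusted p = 0.629 with an estimated correlation. Ribosomal proteins had a median of -0.02 (adjusted p = 0.00863; adjusted p = 0.755 with an estimated correlation), which was 0.04 without day 13. Adjusted over the list alone, 12 phosphate list genes, 6 SPX proteins, 4 purple acid phosphatases, 5 phosphodiesterases and 1 chlorophyll a/b-binding protein were lower, and 4 histones and 1 SPX protein higher. Over all loci GDPD2, a member of both the phosphate and the phosphodiesterase list, was lower, and a histone H4 (Os05g0466600, 0.15) higher. Under quantile normalization the medians of the chlorophyll a/b-binding proteins, photosystem subunits and Calvin cycle genes were -0.004, -0.041 and -0.021.

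The count of loci with a trend depended on single days. It was 4544 without day 13, 61 without day 20, 203 without day 27, 98 without day 34, 116 without day 48, 42 without day 55, 16 without day 62 and 22 without day 69. Without the nitrogen-deficient array of day 13 it was 1394, and within scan day 1 alone, which holds 4 days, it was 0.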

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

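For the calls between nitrogen-deficient and control leaves, the tests of the slide and of the day 13 array alone were chosen only after the result was seen. The same holds for the test of leaf age for the day 13 array and for the 3 tests of the phosphate list in phosphorus-deficient leaves.

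One pattern is the 446 loci called between nitrogen-deficient and control leaves. The nitrogen-deficient array of day 13 alone does not account for all of them, since 241 loci passed without it, not all of these among the 446. Scan day is a candidate explanation. Of the loci ranked highest on the other 5 days, a mean of 35.9% (SD 11.9 over 4 days) had the same sign on the days of scan day 1. With scan day as a block, which rests this comparison on days 13, 20, 27, 41 and 55, 7 loci passed. The median absolute difference of the 446 then went from 0.63 to 0.57 and its SE from 0.15 to 0.18. The 446 were chosen on these same arrays, so their kept size does not speak against scan day. The slide and the omission of nitrogen cannot be told apart, because all slides but the day-20 slide hold a single condition. With the slide as a random block 6 loci passed (median 0.61, SE 0.18). That count lay under the level set, after the result was seen, for the slide as a cause. On the day-20 slide, which holds all conditions, 47.8% of the top loci of the other 8 days kept their sign. This share lay under the level set beforehand for speaking against the omission of nitrogen, but it rests on 1 slide. Over the 9 left-out days the mean was 70.3% (SD 19.8), from 41.3% on day 27 to 94.4% on day 48. Exchanges of conditions within days do not exclude chance, since 9 of 100 gave as many calls, the highest other 1323, and the exchange of the days not on scan day 1 gave 706.

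Another pattern is the nitrogen-deficient leaf of day 13, which lay far from the other samples of its condition, with a score of -116 on principal component 3 and 27.6% of its loci 2-fold or more from the control leaf of that day. Weak labelling is argued against by its 75.7% of spots well above background (70.4% to 76.7% on the other arrays of scan day 1). Its 75th percentile of intensity, 2364, lay above the 1019 to 2054 of those arrays, so another difference in labelling or hybridisation stays open. A leaf further along in age may account for the pattern, since the differences of this leaf correlated across loci at 0.527 with the weekly trend of the other 8 days. Part of this may come from the shared control leaf, as the phosphorus and potassium differences of day 13 correlated at 0.393 and 0.147, and taken against the mean of those 2 leaves in place of the control the correlation was 0.489. A mislabelled array stays open, with a highest correlation to an array of another day of 0.429 (potassium-deficient, day 69) and of 0.410, 0.382 and -0.012 to the phosphorus-deficient, potassium-deficient and control arrays of day 13, and it cannot be told apart from a true sample by these values. The nitrogen response of the other 8 days, correlated at 0.324 across loci, stays open too, as the control leaf is shared and the design has 1 array per condition and day.

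The last pattern is the phosphate starvation response list in phosphorus-deficient leaves, which on day 55 stood at 1.92, far from the other days. Day 55 alone does not account for it, since the mean was 0.26 without that day, with 6 of the other 8 days above 0. Chance over days stays open. The exact sign-flip test over 9 days gave p = 0.0391, and 0.606 adjusted over the 31 lists. The adjusted value cannot decide this, since the smallest p that 9 days allow, 0.00391, is 0.121 adjusted where a single list reaches it. Scan day is argued against, as both conditions shared a scan day on 9 of 9 days, and the mean was 0.557 (SE 0.474) within scan day 1 and 0.473 (SE 0.135) within scan day 2. The slide (mean -0.12 on the day-20 slide, which holds both conditions) and the omission of phosphate, which the design names, stay open.

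On day 13 the nitrogen-deficient leaf also lay far below its other days in 3 lists, with means of -2.24 for purple acid phosphatases, -1.31 for jasmonate genes and -3.43 for the phosphate starvation response. The potassium-deficient leaf of day 48 lay far below its other days for the glycerophosphodiester phosphodiesterases, at -1.88. The potassium-deficient less control difference of day 41 lay far above that of the other days for nitrogen uptake and assimilation, at 0.59. The nitrogen-deficient and phosphorus-deficient leaves stood at similar values that day against the same control array, so the value is not particular to potassium deficiency. Chance gives such a sample in about 1 in 20 groups, which is 2.5 of the 49 groups tested, and 8 were found. The groups share arrays and are not independent, and several of the 8 are the nitrogen-deficient array of day 13. The excess over 2.5 thus counts that array more than once.

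Differences between deficient conditions were called at 441 loci between nitrogen and phosphorus deficiency and at 2 between nitrogen and potassium deficiency. Slopes differed from the control at 231 loci for nitrogen and 3 for phosphorus deficiency. The phosphate starvation response list had a median of 0.62 in phosphorus-deficient less potassium-deficient leaves.

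Exchanges of conditions within days, 100 per comparison with the real one included, were counted for the other results. Few exchanges gave as many calls as the 2 loci between nitrogen and potassium deficiency (3 exchanges, highest other 5) and the 3 loci of the phosphorus slope (2, highest other 3). The same holds for the 434 loci of the trend over orders of the days (4, highest other 854). These shares were not adjusted over the 10 comparisons, so they do not firmly exclude chance. Chance is also not excluded for the 441 loci between nitrogen and phosphorus deficiency (5, highest other 2797). Nor is it for the 231 loci of the nitrogen slope (20, highest other 2613). For the comparisons with 0 calls all 100 gave as many. There the highest other was 1 for phosphorus deficiency against the control, 1434 for potassium deficiency against the control, 15 between phosphorus and potassium deficiency and 561 for the potassium slope. The 1434 came from exchanging the days not on scan day 1, where 1 locus passed between the real conditions with scan day as a block. Counts several times the real ones point to a structure of the samples, whose cause was not tested.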

How the results depend on the processing

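Scan day as a block, scan day 1 alone, the fits without the nitrogen-deficient array of day 13 and the sign-flip test were chosen only after the results were seen. Comparisons are written N, P and K for the 3 deficiencies and C for the control. Counts stayed within 1.5 times the reported one under 6 settings for N against C, 15 for P against C, 11 for K against C, 7 for N against P, 5 for N against K, 12 for P against K, 6 for the N slope, 9 for the P slope, 13 for the K slope (all that were run) and 6 for the trend. The cause of the changes was not tested, except that some settings use fewer arrays or test more loci. Signal over background limits the steepest loci of the trend, which lay near background early where they rose and late for 2 of those that fell.

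With no filter the counts were 249 for N against C, 107 for the N slope and 205 for the trend. With only the 2 conditions compared they were 0 for N against C, 1 for K against C, 1 for N against P, 0 for N against K, 0 for the N slope and 0 for the P slope. With no day term, and with a linear one, N against C, N against P and N against K gave 0. Quantile normalization gave 0 for N against K and 147 for the N slope, and normexp with quantile normalization gave 1 for N against K. The slide as a random block gave 6 for N against C, 0 for N against P and 0 for N against K. The slide as a fixed block, which rests on the day-20 slide with 1 array per condition, gave 60, 61 and 19 for N, P and K against C, 93 for N against P, 18 for N against K and 33 for P against K. Early against late days gave 0 for the N and P slopes. For the trend, the control alone gave 1022 and day as a random block 2651.

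Scan day as a block gave 7 for N against C, 1 for K against C, 0 for N against P, 0 for N against K, 1 for P against K and 0 for the N slope. Scan day 1 alone gave 3 for N against C, 151 for K against C, 0 for N against P, 1 for N against K, 6 for P against K and 0 for the N slope, the P slope and the trend. Without the nitrogen-deficient array of day 13 the counts were 241 for N against C (191 of them among the 446), 213 for N against P, 0 for N against K, 2 for the N slope, 7 for the P slope and 1394 for the trend. Without day 13 and with the slide as a random block N against C gave 1.

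Leaving out each day in turn gave 13 to 1056 for N against C, 0 to 1085 for N against P, 0 to 8 for N against K, 0 to 1 for P against K, 2 to 977 for the N slope, 0 to 21 for the P slope and 16 to 4544 for the trend. Of 59 list calls, 0 passed with an estimated correlation, and fry called 5 lists, of which 4 were among the 59 (the other was heat shock proteins for N against P, fry adjusted p = 0.0395, camera adjusted p = 0.132). Of the 43 in the 6 comparisons of conditions 0 passed the exact sign-flip test. With 9 days that test could hardly be passed, as lists of 1 sign on 9 of 9 days had adjusted p of 0.0605 or 0.121. With the slide as a fixed block, N against C turned for Os12g0512000 (-0.29), Os12g0603700 (-0.038), Os10g0529700 (-1.02), Os05g0579600 (-0.15), Os05g0191500 (0.14), Os03g0102700 (0.45) and Os10g0555700 (2.87).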

Other observations

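Single members of lists that did not pass as a whole were called between nitrogen-deficient and control leaves. The clock gene PRR1 (Os02g0618200) was higher by 0.36 ± 0.09 on the log2 scale (adjusted p = 0.0307 in limma, 9 of 9 days), a WRKY factor (Os05g0129800) by 0.43 ± 0.10 (8 of 9 days) and glutathione S-transferase Os01g0692100 by 0.61 ± 0.15 (9 of 9 days). Of the DnaJ proteins in the heat shock list, Os03g0837700 was higher by 0.89 ± 0.21 and Os01g0875700 lower, at -0.88 ± 0.20.

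On day 41 the mean of the nitrogen uptake and assimilation list was above the control by 0.59 in nitrogen-deficient, 0.60 in phosphorus-deficient and 0.59 in potassium-deficient leaves, with 20, 22 and 23 of 25 members higher. These 3 values share 1 control array. That array had the lowest 75th percentile of intensity (1019) and the lowest share of spots well above background (70.4%) on scan day 1.

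Of the 569 probes without a locus, 132 were tested and none was called against the control in limma. At an unadjusted p under 0.05 there were 13 for nitrogen, 1 for phosphorus and 16 for potassium deficiency.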
